A study of Mus musculus with 2 samples.

How the data were processed

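RNA was sequenced from 2 sorted cell populations of mouse cortex at embryonic day 15.5, NPCs and neurons, with 1 library each. Per the labels' protocols, cortices of embryos carrying a Nestin-driven green and a doublecortin-driven red reporter were dissociated mechanically with EDTA and DNase I, sorted by fluorescence, and total RNA was extracted with TRIzol before library preparation with an Illumina TruSeq RNA kit. The submitters' processing notes name CASAVA 1.9, TopHat 1.2.0, SAMtools 0.1.18, edgeR without a version and the mouse genome build mm9, with no role or order given. Whether reads were counted by strand, how reads that align to several places were treated and which gene annotation was used are not given in the sources used here. Reads of near-identical genes (the globin copies, Rpl29, Gapdh and Ppia with their processed pseudogenes, and the alpha protocadherins, which share exons) could have been split, multiplied or lost, so values of these genes are uncertain.

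Each file lists 20373 genes by symbol in the same order, with 1 value per gene and no coordinates, so none are printed. The deposited values are a signal never below 0 and are not whole numbers, but in each library they are whole multiples of a single step, 0.952727 in the NPC library and 1.12797 in the neuron library, which is the form of read counts rescaled to a common library size. Dividing by the step gave whole reads within 0.05 reads for 100% of the NPC values and 99.9656% of the neuron values, and the recovered reads summed to 26346226 and 23312054. Neuron values under 0.01 were taken as 0. The ratio of the steps, 1.18394, lies near the ratio of effective library sizes, 1.18086, obtained here from trimmed mean of M-values (TMM) factors of 1.02219 and 0.978294 with edgeR 4.0.16 in R 4.3.3. The ratio of total reads, 1.13015, lies farther away, and the authors' scaling between the libraries was kept. The 10 most abundant genes took 2.61% and 3.34% of the reads. Each of 3 symbols stands on 2 rows.

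The analysis had been laid out for counts or for values already scaled to a fixed total. Because the deposited values lie on the scale of reads, both libraries were divided by the same constant, the mean of their sums (25698104 reads), and multiplied by 1000000. This gives CPM and leaves the ratio between the libraries as deposited. On this scale 1 CPM is 26.97 reads in the NPC library and 22.8 in the neuron library. Genes with at least 1 CPM in at least 1 library were compared by log2((neuron + 1)/(NPC + 1)), which understates the difference of low genes, and counted from 2-fold upward. Folds printed for single genes are the ratio of the CPM values without the added 1. Each has an exact 95% Clopper-Pearson interval for the share of the gene's recovered reads that came from 1 of the libraries, converted to a ratio. Reads without molecular identifiers are not independent molecules, so intervals and the 3-read floor cover counting error only. A test on the reads of 2 libraries compares those libraries, not the cell types, and no p-value was computed.

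Before the data were examined, 31 gene lists with 542 genes, the filter, the thresholds and the processing alternatives were fixed. The unit of the filter and of the added 1, CPM, was settled only after the form of the deposited values was seen. The rule for named genes was also fixed before the data were examined. It takes Nes and Dcx, then up to 4 members per list with the largest absolute log2 ratio among those past the filter, the most abundant members of lists for other cell types, and the 10 genes with the largest log2 ratio in each direction among genes at 10 CPM or more in a library, leaving out predicted, LOC, microRNA, small nucleolar and Riken symbols. Of 9950 genes at that level, 476 were left out by symbol. Other genes are named only with the statement that they were chosen after their values were seen. Some genes that the rule names are not reported here. For 15 list members an older symbol was used, found through the synonyms of the RefSeq table of GRCm38.p6 or written in the list, and 1 member, Setd1b, was not found. The lists cover radial glia, intermediate progenitors, neuronal transcription factors, cytoskeleton, axon guidance, synapses, ion channels, the cell cycle, Notch, polymerase pausing, chromatin regulators, splicing, stress, metabolism, reference genes and 9 other cell types. For each list the median log2 ratio was set among those of 10000 random lists of the same size matched on mean expression in 20 bins. Lists whose median lies outside the central 95% stand apart from such lists in these libraries, which is a description of the libraries and not a test of the cell types. The medians of 19 of the 29 lists with members past the filter lay outside that range. The range of each median was found by resampling its members 10000 times.

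The calculations were tested on simulated data for this comparison, drawn over 20373 genes from the real means and library sizes with counting error only. Variation between preparations was not simulated, so the simulation gives no rate of false calls for the real libraries. True differences were given only to genes well above the filter, so detection near 1 CPM was not tested. All 50 genes at each of the true log2 ratios of 1.5, −1.5, 3 and −3 were counted as at least 2-fold different in the right direction, and 0 of 12334 unchanged genes passed 2-fold. Of the counting intervals, 95.9% of 1000 held the true fold, reads were recovered exactly for all 40746 values, and 14 of 200 random lists fell outside the central 95%. Alternatives changed the scaling, the pseudocount, the filter, the fold threshold and the matching of random lists. Transcript lengths came from GENCODE M21 on GRCm38, matched by symbol, and were used only for a check of length. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.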

Results

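Gene expression was measured by RNA sequencing in 2 cell populations sorted from the cortex of mouse embryos at embryonic day 15.5, a stage at which radial glia and intermediate progenitors of the cortical wall produce neurons for the upper cortical layers. The embryos carried a green reporter under regulatory sequences of Nestin, which mark neural progenitor cells (NPCs), and a red reporter under those of doublecortin (Dcx), which mark young neurons. Per the labels, green cells were taken as NPCs and cells with both colours as neurons. There was 1 library of each population. The NPC library held 26346226 reads on listed genes and the neuron library 23312054. In these libraries 15657 and 15455 of the 20373 listed genes had at least 1 read. The series relates the transcriptomes of NPCs and their daughter neurons to RNA polymerase II pausing and to histone H3 methylation. Those other assays were not analysed here, and the comparison is that of transcript levels between the NPC and the neuron library. Levels are given in CPM (counts per 1000000).

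Transcripts of radial glia, of intermediate progenitors, of the Notch pathway and of the dividing cell were more abundant in the NPC library, with list medians from 2.11-fold to 3.05-fold. Transcripts for the neuronal cytoskeleton, synapses and ion channels were more abundant in the neuron library, with list medians from 1.71-fold to 1.88-fold. With 1 CPM added to both values, some other cell types had larger list medians on each side. The pericyte and oligodendrocyte lineage medians were 9.22-fold and 5.86-fold higher in NPCs. Those of microglia and Cajal-Retzius cells were 3.30-fold and 2.79-fold higher in neurons. Most other genes lay close to equal. Of 12693 genes with at least 1 CPM in at least 1 library, and with 1 CPM added to both values, 489 were at least 2-fold higher in neurons (3.85%) and 854 at least 2-fold higher in NPCs (6.73%), while 11350 (89.4%) lay within 2-fold. On the same scale, at least 4-fold differences were found for 13 genes higher in neurons and 62 higher in NPCs, and at least 8-fold differences for 0 and 19 genes. Counts of list members at least 2-fold apart are on this scale too. Folds of single genes are given without the added value and run larger for low genes. The median log2 ratio of neuron to NPC was −0.0049, with the 5th percentile at −1.17 and the 95th at 0.90. Pearson's r of the log2 values was 0.961 across genes, which are not independent replicates. With 1 library per group these differences have no replicate check and no p-value, and the 95% intervals beside folds cover counting error only. The counts depend on the value added before the logarithm and on the filter. With 5 CPM added in place of 1 they were 238 and 399, and with both the added value and the filter at 1 on the deposited scale, where 1 unit is close to 1 read, they were 1553 and 1800.

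**Figure D1:**
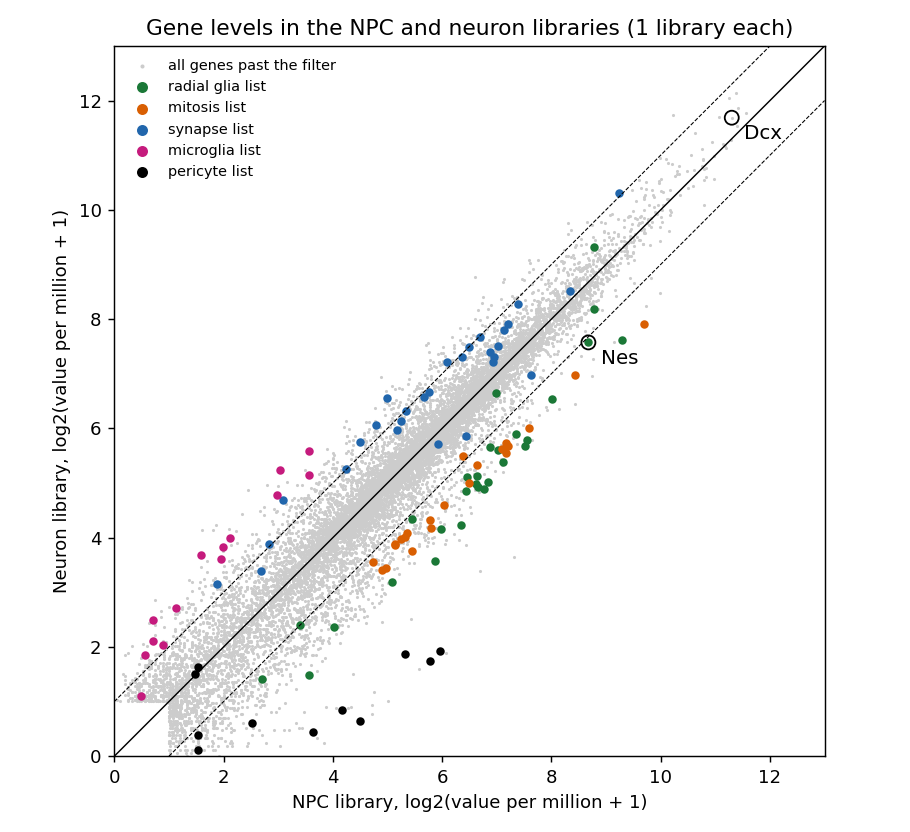
Level of each gene past the filter in the NPC library (horizontal axis) and the neuron library (vertical axis), both as log2(CPM + 1), with 1 library per axis. The solid line marks equal levels, the dashed lines mark 2-fold differences on this scale, and coloured points are the members of 5 gene lists. Most mitosis and radial glia genes and 9 of 11 pericyte genes lie below the lower dashed line, microglia genes lie above the diagonal, and Dcx (2522 and 3294 CPM) lies near it.

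The 2 genes whose regulatory sequences drove the sorting reporters were examined first. Nes, which encodes the intermediate filament of progenitors, was at 408.5 CPM in NPCs and 189.5 in neurons, 2.16-fold higher in NPCs (95% counting interval 2.08 to 2.23). Dcx, a microtubule-binding protein of migrating neurons, was at 2522 CPM in NPCs and 3294 in neurons, 1.31-fold higher in neurons (1.29 to 1.32). The log2 ratio of Dcx was 0.39. It was the gene of rank 5 by level in the NPC library and of rank 7 in the neuron library.

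Progenitor genes were lower in the neuron library almost throughout. Of 28 measured radial glia and neural stem cell genes, 24 were at least 2-fold higher in NPCs and 0 in neurons, with a median log2 ratio of −1.61. Ednrb, the endothelin receptor B, was at 57.2 CPM in NPCs and 10.9 in neurons (5.24-fold, 4.58 to 6.01). Hes1, a repressor of neuronal differentiation downstream of Notch, was at 10.8 and 1.80 (5.99-fold, 4.31 to 8.53). The secreted glycoprotein gene Mfge8 and the transcription factor gene Sox3 were 4.49-fold (4.04 to 5.01) and 4.03-fold (3.44 to 4.75) higher in NPCs. Among members chosen after their values were seen, the transcription factor genes Pax6 and Sox2 were 3.38-fold and 2.88-fold higher in NPCs. Ptprz1, a receptor phosphatase also chosen in this way, was the 1 member higher in neurons (436.4 and 641.4 CPM, 1.47-fold). Of 13 intermediate progenitor genes, 7 were at least 2-fold higher in NPCs and all 13 were higher there, with a median of −1.21. Neurog2, a proneural factor, was at 502.1 and 170.0 CPM (2.95-fold, 2.85 to 3.06). Its relative Neurog1 was 4.22-fold higher in NPCs (3.51 to 5.10). Eomes, also chosen after its value was seen, was at 1013 and 353.6 CPM (2.87-fold). Of 20 Notch pathway genes, 5 of which belong to other lists as well, 11 were at least 2-fold higher in NPCs, with a median of −1.09. Notch1 was at 342.3 and 86.2 CPM (3.97-fold, 3.78 to 4.17). Notch3, which mural cells of blood vessels also make, was at 85.8 and 13.5 (6.35-fold, 5.63 to 7.17), and the target gene Heyl at 9.08 and 0.527 (17.2-fold, 9.69 to 33.8). The ligand gene Jag2 was the 1 Notch member at least 2-fold higher in neurons, at 7.79 and 23.4 CPM (3.01-fold, 2.56 to 3.55; chosen after its value was seen). The medians of all 3 lists lay at percentile 0 of random lists matched on expression, which describes these libraries only. Markers of pericytes and endothelium moved with these progenitor groups, with median log2 ratios of −3.20 and −1.25.

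Cell cycle genes were lower in the neuron library but remained readily measured there. Markers of pericytes, endothelium and the oligodendrocyte lineage were lower in the same library, with median log2 ratios of −3.20, −1.25 and −2.55. Of 22 mitosis and G2/M genes, 21 were at least 2-fold higher in NPCs, with a median log2 ratio of −1.46. Kif20a, a mitotic kinesin named after its value was seen, was the exception at 1.87-fold. Mki67, the gene of the Ki-67 proliferation antigen, was at 829.5 CPM in NPCs and 241.1 in neurons (3.44-fold, 3.34 to 3.54). Hmmr, Bub1 and Cenpe, which act on the spindle and at kinetochores, were 3.42-fold, 3.17-fold and 3.08-fold higher in NPCs. The median member of this list was present in the neuron library at 35.7% of its NPC level. Of 20 DNA replication and G1/S genes, 13 were at least 2-fold higher in NPCs and all 20 were higher there, with a median of −1.07. Both lists stood at percentile 0 of random lists. Cdc6 and Cdt1, which load the replicative helicase, were 3.85-fold (3.11 to 4.80) and 2.98-fold (2.51 to 3.56) higher in NPCs. The helicase subunit gene Mcm3 was at 96.5 and 28.8 CPM (3.35-fold, 3.07 to 3.65). The cell cycle exit list had a median of −0.062, at percentile 25.2 of random lists. At least 2-fold higher in NPCs were 3 of its 11 measured members, Gas1 (4.34-fold, 3.93 to 4.79), the CDK inhibitor gene Cdkn2c (2.74-fold) and the retinoblastoma relative Rbl1 (2.40-fold). Cdk5r1, the activator of the neuronal kinase Cdk5, was 1.87-fold higher in neurons (1.83 to 1.92).

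Genes for the neuronal cytoskeleton, synapses and excitability were more abundant in the neuron library. All 24 members of the neuronal cytoskeleton and axon growth list were higher in neurons, 8 of them at least 2-fold, with a median log2 ratio of 0.87. The neurofilament genes Nefl (2.52 CPM in NPCs and 16.7 in neurons) and Nefm (17.98 and 69.4) were 6.63-fold (5.11 to 8.72) and 3.86-fold (3.49 to 4.28) higher in neurons. Cntn2, an axonal adhesion molecule, and Stmn2, a microtubule regulator of growth cones, were 2.86-fold and 2.83-fold higher. Of 29 synapse and transmitter release genes, 10 were at least 2-fold higher in neurons, with a median of 0.91. Grin1, the obligatory NMDA receptor subunit, was at 7.49 and 24.9 CPM (3.32-fold, 2.83 to 3.92), and the scaffold gene Dlg2 at 30.9 and 92.8 (3.002-fold, 2.77 to 3.26). The vesicle genes Sv2b and Cplx1 were 2.94-fold and 2.45-fold higher. Lower in neurons were 3 members, picked out after their values were seen. They were Slc17a6, a vesicular glutamate transporter (197.3 and 125.0 CPM), the kainate receptor gene Grik2 (85.9 and 57.2) and the synapsin gene Syn2 (59.99 and 51.4). Of 20 voltage-gated ion channel genes, 9 were at least 2-fold higher in neurons, with a median of 0.77. Kcna1, Cacna1c, Scn2a1 and Scn3b, for subunits of potassium, calcium and sodium channels, were 2.65-fold, 2.56-fold, 2.52-fold and 2.49-fold higher. Cortical layer and neuronal transcription factors had a smaller median of 0.33, at percentile 99.9 of random lists, against percentile 100 for the cytoskeleton, synapse and channel lists. In this list 4 of 24 were at least 2-fold higher in neurons, among them the following 3. Bhlhe22 was at 105.7 and 312.4 CPM (2.96-fold, 2.83 to 3.09). Myt1l and Mef2c were 2.51-fold and 2.24-fold higher. Axon guidance genes went both ways, with a median of 0.11 at percentile 86.3 of random lists. Ephb1, Robo1 and Plxnd1 were 2.44-fold, 2.33-fold and 2.19-fold higher in neurons, and the guidance cue gene Ntn1 was 3.43-fold higher in NPCs (2.35 to 5.11). Markers of microglia and of Cajal-Retzius cells moved with these neuronal groups, with median log2 ratios of 1.72 and 1.48.

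**Figure D2:**
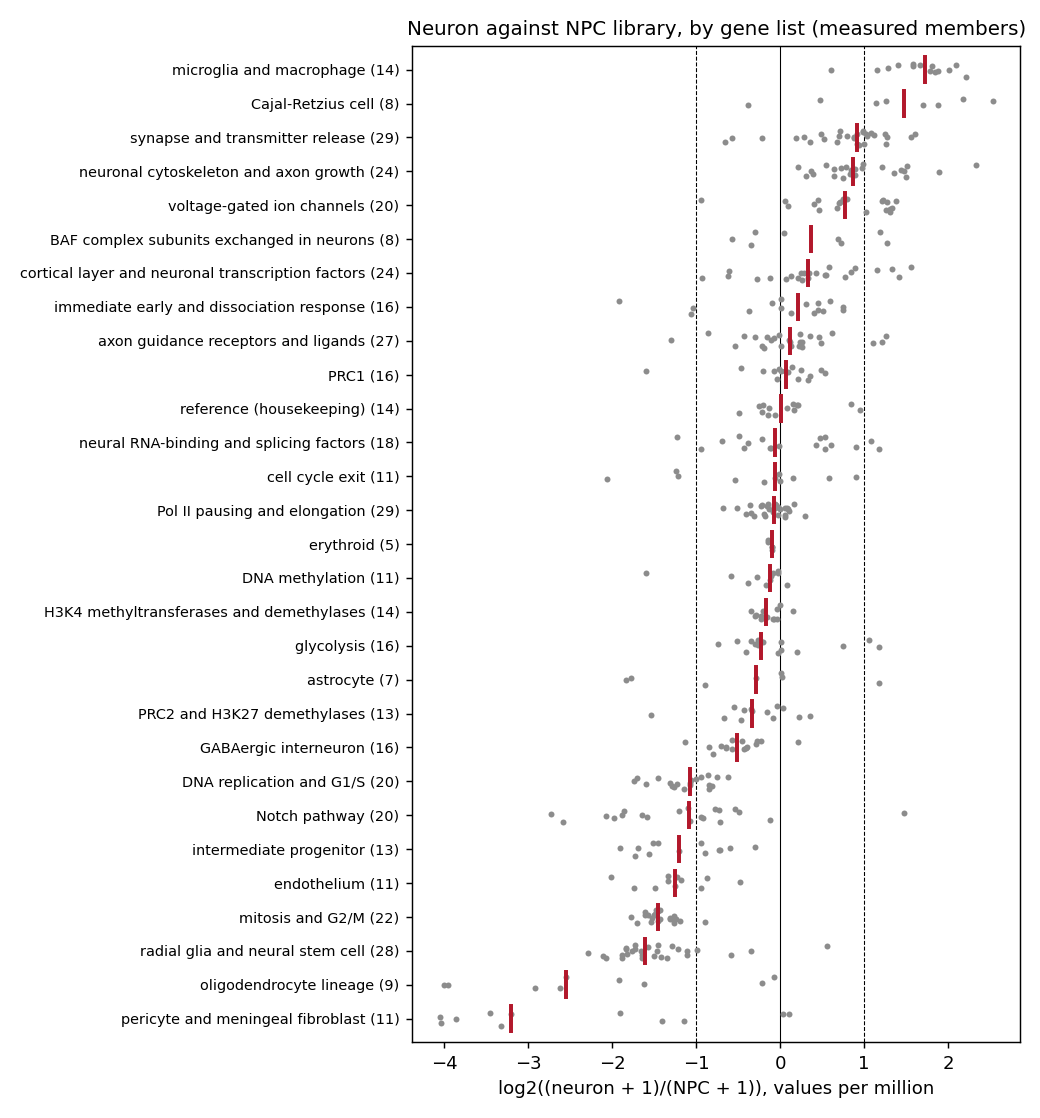
Log2((neuron + 1)/(NPC + 1)) of CPM values (horizontal axis) for each measured member (grey points) of the 29 gene lists with members past the filter, with the number of members in brackets. Red bars mark list medians and dashed lines 2-fold differences. Medians run from −3.20 for pericyte and meningeal fibroblast genes to 1.72 for microglia and macrophage genes, and the Pol II pausing and elongation genes all lie within 2-fold.

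The factors that pause and release RNA polymerase II, which the series is about, differed little in transcript level. Of 29 measured genes of the pausing and elongation list, 0 were 2-fold different in either direction, and the median log2 ratio was −0.072, at percentile 8.79 of random lists. Cdc73, a subunit of the PAF1 complex, was at 55.4 and 34.2 CPM (1.62-fold higher in NPCs, 1.48 to 1.77). Larp7 of the 7SK particle and the kinase gene Cdk12 were 1.44-fold (1.31 to 1.58) and 1.33-fold (1.26 to 1.41) higher in NPCs. Whsc2, the NELF-A subunit of the negative elongation factor, was at 40.8 and 31.7 (1.29-fold, 1.17 to 1.42). Cdk9, the kinase of P-TEFb that releases paused polymerase, was at 67.7 and 71.5 CPM (1.06-fold higher in neurons, 0.988 to 1.13). Supt5h, a DSIF subunit, was at 192.4 and 188.6 (1.02-fold higher in NPCs, 0.980 to 1.06). Both were chosen after their values were seen, and no difference of either was detectable beyond counting error.

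Writers and erasers of the bivalent marks H3K27 and H3K4 methylation were slightly lower in neurons as groups. In the same library, markers of pericytes, endothelium and the oligodendrocyte lineage were lower too, with median log2 ratios of −3.20, −1.25 and −2.55. The PRC2 and H3K27 demethylase list had a median log2 ratio of −0.33, at percentile 0.095 of random lists, with 10 of 13 members higher in NPCs and 1 of them at least 2-fold. That member was Phf19, a PRC2 accessory subunit, at 5.34 and 1.19 CPM (4.50-fold, 2.97 to 7.07). Aebp2, another accessory subunit, was 1.60-fold higher in NPCs (1.48 to 1.73), and the H3K27 demethylase gene Kdm6a 1.48-fold (1.38 to 1.57). The catalytic subunit gene Ezh2, chosen after its value was seen, was at 240.8 and 189.2 CPM (1.27-fold, 1.22 to 1.32). The H3K4 methyltransferase and demethylase list had a median of −0.17, and 0 of 14 members reached 2-fold. This median was at percentile 1.14 of random lists matched on expression and 6.63 of unmatched ones. Kdm5c and Mll3 were 1.27-fold and 1.23-fold higher in NPCs. PRC1 genes had a median of 0.075, at percentile 77.9 of random lists, and a single member at least 2-fold apart, Pcgf5, at 5.75 and 1.23 CPM (4.67-fold higher in NPCs, 3.11 to 7.27). DNA methylation genes had a median of −0.12, at percentile 10.2, and 1 of 11 reached 2-fold. This was Uhrf1 (107.8 and 35.03, 3.08-fold higher in NPCs, 2.84 to 3.33), which brings the maintenance methyltransferase to replicating DNA and is also in the replication list. Dnmt3a was 1.51-fold higher in NPCs (1.44 to 1.59). Among 8 subunits of the BAF remodelling complex that are exchanged as progenitors become neurons, the neuronal subunit genes Dpf1 and Actl6b were 2.44-fold (2.30 to 2.59) and 2.32-fold (2.15 to 2.51) higher in neurons. The median of this list was 0.37 (resampling range −0.35 to 1.19), at percentile 99.1 of random lists, and 0.051 with a minimum of 10 CPM in place of 1. Of its members 5 were higher in neurons and 3 in NPCs, or 4 and 4 with scaling by total reads. The list pools progenitor and neuronal subunits, so its median is no measure of their exchange.

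Developmental regulators of other lineages, which textbooks list as Polycomb targets, were near silence in both libraries. Of 44 such genes, 31 had 0 reads in both libraries, 40 had at most 3 reads in each, and the highest value was 0.890 CPM, so that none passed the filter. The 17 Hox genes among them had at most 1 read in a library. A count of 3 reads corresponds to 0.111 CPM in the NPC library and 0.132 in the neuron library, and differences below these levels were not detectable.

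Splicing and metabolic genes showed member-specific differences. The neural RNA-binding and splicing list had a median of −0.060, at percentile 15.3. In this list Rbfox1 (2.27-fold, 2.15 to 2.40) and Celf5 (2.12-fold) were higher in neurons. Qk (371.2 and 158.6 CPM, 2.34-fold, 2.25 to 2.43) and the splicing repressor gene Ptbp1 (1.93-fold, 1.84 to 2.02) were higher in NPCs. The glycolysis list had a median of −0.23 (resampling range −0.30 to 0.089), at percentile 0.21 of random lists. Of its 16 members, 6 were higher in neurons and 10 in NPCs. The phosphofructokinase gene Pfkp (2.33-fold, 2.10 to 2.59) and the neuronal enolase gene Eno2 (16.3 and 34.9, 2.14-fold) were higher in neurons, and the hexokinase gene Hk2 was 1.69-fold higher in NPCs. Immediate early and dissociation response genes had a median of 0.22, at percentile 96.7, and of 0.012 without the filter and 0.40 with a minimum of 10 CPM. The 3 members at least 2-fold apart on the scale with 1 CPM added were higher in NPCs. These were Egr1 (3.45 and 0.176 CPM, 19.6-fold, 7.42 to 73.6), Arc (3.13-fold, 1.98 to 5.14) and Jun (85.05 and 40.8, 2.08-fold, 1.93 to 2.25). Without the added value Klf4 (0.927 and 2.24) was 2.42-fold higher in neurons (1.47 to 4.07). The 14 housekeeping genes had a median of 0.0047 at percentile 47.9, with 0 members at least 2-fold apart on the scale with 1 CPM added. Without it B2m, a subunit of MHC class I molecules (4.75 and 10.05), was 2.12-fold higher in neurons (1.70 to 2.65). The sign of this median turned when total reads or upper quartiles were used for scaling.

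Markers of other cell types were measured beside these groups. All 14 microglia and macrophage genes were higher in the neuron library, with a median log2 ratio of 1.72. With 1 CPM added 13 of them were at least 2-fold higher, and without it the folds of all 14 ran from 2.80 to 7.32. Csf1r, the receptor that microglia need to survive, was at 10.9 and 46.8 CPM (4.31-fold, 3.78 to 4.92). The perforin-like gene Mpeg1 was at 7.19 and 37.0 (5.14-fold, 4.39 to 6.04) and the complement gene C1qc at 2.00 and 11.8 (5.90-fold, 4.39 to 8.05). Of 8 Cajal-Retzius genes, 6 were at least 2-fold higher in the neuron library, with a median of 1.48. Reln, which guides cortical layering, was at 95.8 and 434.2 CPM (4.53-fold, 4.34 to 4.74), and Trp73 at 2.04 and 16.5 (8.12-fold, 6.10 to 10.98). Pericyte and meningeal fibroblast genes were higher in the NPC library, 9 of 11 at least 2-fold, with a median of −3.20. Pdgfrb, the pericyte growth factor receptor, was at 54.0 and 2.33 CPM (23.2-fold, 17.7 to 31.1), and Abcc9, a potassium channel subunit, at 61.5 and 2.81 (21.9-fold, 17.1 to 28.6). Rgs5 was at 39.15 and 2.68 (14.6-fold, 11.3 to 19.3) and Vtn at 21.7 and 0.571 (37.98-fold, 22.1 to 71.8). All 11 measured endothelial genes were higher in the NPC library, 8 of them at least 2-fold, with a median of −1.25. The VEGF receptor gene Kdr was at 4.82 and 0.439 CPM (10.97-fold, 5.78 to 23.4). The most abundant member, Slc2a1, which many cell types express, was 1.40-fold higher in NPCs. Oligodendrocyte lineage genes had a median of −2.55, with 7 of 9 at least 2-fold higher in the NPC library. Cspg4 (31.2 and 1.01) and Pdgfra (25.3 and 0.703), which pericytes and meningeal fibroblasts respectively also make, were 30.9-fold and 35.98-fold higher. Olig1 (9.82 and 0.439) and Olig2 (7.60 and 0.395) were 22.4-fold and 19.2-fold higher. Against random lists the microglia and Cajal-Retzius medians lay at percentile 100 and the pericyte, endothelium and oligodendrocyte lineage medians at percentile 0. These low genes depend on the added value, and with 5 CPM in place of 1 the medians were 1.12 for microglia, 0.55 for Cajal-Retzius cells, −1.62 for pericytes, −0.43 for endothelium and −1.22 for the oligodendrocyte lineage. Without the filter the pericyte median was −1.90.

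Further cell types differed less. GABAergic interneuron genes had a median log2 ratio of −0.51, at percentile 0.13 of random lists, and 1 of 16 reached 2-fold, Dlx6 (2.15 and 0.439 CPM). The most abundant, Dlx1, was at 105.3 and 70.4 (1.495-fold higher in NPCs, 1.41 to 1.59). The astrocyte list, of which 6 of 10 genes are also made by other cells of the cortex, had a median of −0.28 at percentile 7.22 of random lists. Its median was −0.16 without the filter and −0.14 with a minimum of 10 CPM. Gja1 and Aldh1l1, which radial glia also express, were 3.90-fold and 4.25-fold higher in NPCs, and Apoe, a gene of macrophages as well, was 2.35-fold higher in neurons (2.07 to 2.67). The 5 measured erythroid genes had a median of −0.094, at percentile 30.3, with 0 at least 2-fold apart. The alpha globin gene Hba-a1 was at 60.7 and 56.9 CPM, and it is uncertain because the near-identical globin copies carry the same values. None of the 7 choroid plexus genes reached 1 CPM.

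**Figure D3:**
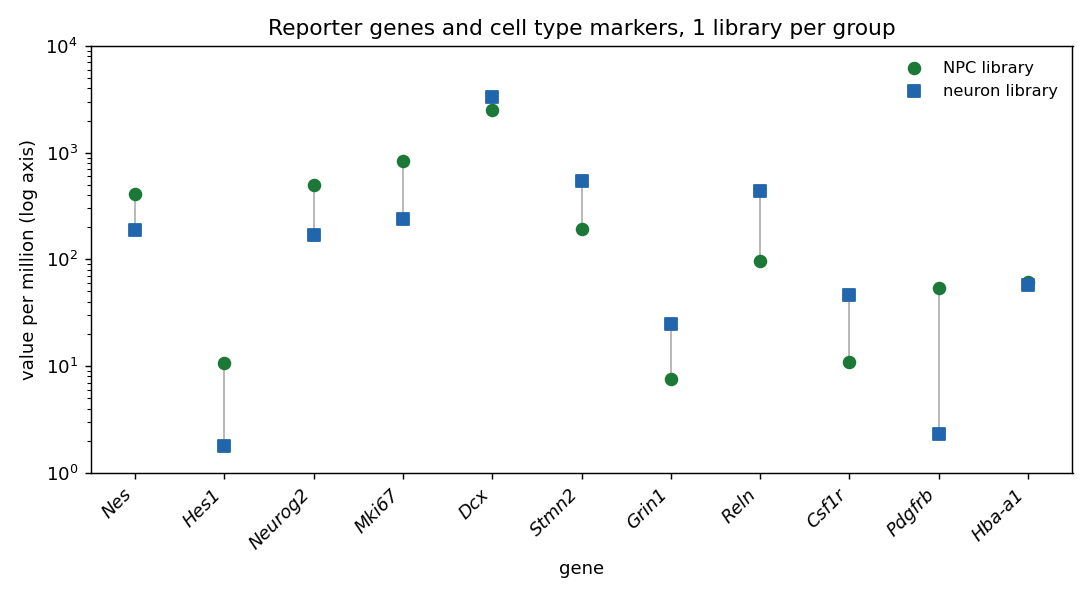
Level in CPM (vertical log axis) of the reporter genes Nes and Dcx and of 9 markers in the NPC library (green circles) and the neuron library (blue squares), 1 library per group, with a grey line joining the values of a gene. Csf1r is 4.31-fold higher in neurons, Pdgfrb is 23.2-fold higher in NPCs, and Hba-a1 is at 60.7 and 56.9.

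Among genes at 10 CPM or more in a library, those with the largest log2 ratios included members of the lists for these other cell types. Which cells supplied their transcripts was not measured. Of the 10 named genes leading in neurons, Mpeg1 and C1qc are on the microglia list and Trp73 and Reln on the Cajal-Retzius list, and Fcrls and Sepp1 are known from microglia and macrophages. The others were Nefl, Fam19a2, which encodes a secreted brain peptide (4.45 and 28.3 CPM, 6.35-fold, 5.22 to 7.79), the acid-sensing channel gene Accn1 (3.299 and 16.9, 5.14-fold, 4.07 to 6.54) and Rpl29. The value of Rpl29, a ribosomal protein gene (6.77-fold, 5.25 to 8.84), is uncertain because pseudogene copies share its sequence. The 10 leading in NPCs, none from the radial glia, intermediate progenitor, Notch or cell cycle lists, included Pdgfrb, Abcc9, Vtn, Cspg4 and Pdgfra. They also included the basement membrane genes Nid1 (66.1 and 2.72, 24.3-fold, 18.9 to 31.8), Col4a1 (157.9 and 11.5, 13.7-fold, 12.1 to 15.6) and Lamc3 (13.3 and 0.176, 75.6-fold, 29.4 to 280). The growth factor gene Igf2 was at 46.8 and 2.02 (23.2-fold, 17.3 to 31.8) and the matrix protease gene Mmp9 at 25.4 and 0.922 (27.5-fold, 17.9 to 44.8).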

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

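Chosen only after the data were seen were the alternatives on the deposited scale, with the whole counting interval beyond 2-fold, and with TMM factors computed again. No called direction turned under any setting: of 261 list medians recomputed under 9 settings, 242 stayed within the resampling range of the median, 19 moved outside it, and 0 of the lists outside the central 95% of random lists changed sign. The erythroid median, which was not outside that range, was −0.094 and became 0.33 on the deposited scale, where very low genes enter. An added value cannot change the sign of a gene's ratio, and scaling shifted all genes nearly alike and by little. These settings could therefore hardly turn a called direction. The resampling range reflects the spread among members, so a list with a wide range can move far and still count as within it. The erythroid range was narrow, −0.145 to −0.093, and small shifts counted as moved. Its members include globin copies that carry the same values and were resampled as separate genes.

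Against 489 genes higher in neurons and 854 higher in NPCs, pseudocount 5 gave 238 and 399 and pseudocount 0.1 gave 725 and 1110. The deposited scale, which lowers the added value and the filter together, gave 1553 and 1800. The 4-fold threshold gave 13 and 62, while a minimum of 10 CPM gave 358 and 548. The whole counting interval lay beyond 2-fold for 402 and 738, and TMM factors computed again gave 477 and 851. Scaling by total reads moved the median of all genes to −0.069, the mitosis median from −1.46 to −1.52, the H3K4 median from −0.17 to −0.24, the erythroid median to −0.16, Nes to −1.17 and Dcx to 0.32, as a shift of all genes does. The erythroid median was −0.092 with median-of-ratios size factors and −0.026 with no filter. Without the filter the pericyte median went from −3.20 to −1.90, inside its wide resampling range of −3.85 to −1.14. Pseudocount 5 drew medians toward 0 (mitosis −1.29, microglia 1.12, endothelium −0.43, erythroid −0.087), and pseudocount 0.1 drew them away from it (microglia 2.12, endothelium −2.31, erythroid −0.15, Cajal-Retzius 2.21, oligodendrocyte lineage −3.96), as an added value does by construction. On the deposited scale, microglia were at 2.14, endothelium at −2.47 and Cajal-Retzius cells at 2.22, and with a minimum of 10 CPM endothelium was at −0.47. Without matching on expression, 27 of 29 lists kept their side of the central 95%; the H3K4 list went from percentile 1.14 to 6.63 and the immediate early list from 96.7 to 98.1, and the cause was not tested. Handling of genes listed in one file only gave no value because both files list the same genes, and no replicate could be left out with 1 library per group. Depth limits low genes, since 1 CPM rests on 26.97 and 22.8 reads.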

Other observations

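All tests of explanations given here were chosen only after the result was seen, except that of transcript length, and the gene families were picked after their values were seen. Counts of genes at least 2-fold apart are on the scale with 1 CPM added. Of 28 collagen genes past the filter, 18 were at least 2-fold higher in NPCs and 0 in neurons, 4 were higher in neurons by less, and the median log2 ratio was −1.43. Col4a2, a partner of Col4a1 in basement membranes, was at 102.7 and 9.53 CPM (10.8-fold, 9.38 to 12.4). Of 8 laminin genes, 6 were at least 2-fold higher in NPCs. Markers of pericytes and meningeal fibroblasts, which make many of these proteins, moved with both families (median −3.20, 9 of 11 at least 2-fold higher in NPCs), as did those of endothelium (median −1.25). Of 9 Frizzled receptor genes, which receive Wnt signals, all were higher in NPCs, 2 of them at least 2-fold, or 4 without the added value. The former were Fzd6 (5.60 and 1.01 CPM, 5.54-fold, 3.56 to 9.01) and Fzd8 (73.5 and 23.3, 3.15-fold, 2.86 to 3.48). Of 13 Sox genes, 9 were at least 2-fold higher in NPCs, among them Sox9 (62.4 and 16.8, 3.72-fold) and Sox21 (58.0 and 17.0, 3.41-fold), and 4 were higher in neurons by less, among them Sox5 (1.86-fold). Of 4 Id genes, inhibitors of basic helix-loop-helix factors, 3 were at least 2-fold higher in NPCs, Id1, Id3 and Id4 (3.61-fold, 3.18-fold and 3.20-fold). The exception, Id2, was at 137.7 and 298.6 CPM, 2.17-fold higher in neurons (2.08 to 2.26). The markers of pericytes and endothelium, and those of the oligodendrocyte lineage (median −2.55), also moved with the Frizzled, Sox and other Id genes.

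Among signalling genes higher in neurons, 4 of 10 GABA receptor subunit genes were at least 2-fold higher, led by Gabra2 (3.71 and 16.5 CPM, 4.44-fold, 3.55 to 5.59) and Gabbr2 (3.37 and 14.4, 4.28-fold, 3.38 to 5.46). Of 13 calcium and calmodulin-dependent kinase genes and their relatives, 6 were at least 2-fold higher in neurons and 2 at least 2-fold higher in NPCs. The 6 included Camk2b (28.6 and 121.2, 4.24-fold, 3.91 to 4.5997), Camk4 (30.8 and 87.3, 2.83-fold) and, among the relatives, Camk2n2 (11.1 and 24.8, 2.23-fold). The 2 higher in NPCs were Camk2d (13.1 and 5.09, 2.57-fold, 2.08 to 3.20) and Camk2a (14.4 and 5.88, 2.45-fold). Of 34 kinesin genes, 13 were higher in neurons, all by less than 2-fold, and 21 in NPCs, with a median of −0.41. At least 2-fold higher in NPCs were 12, several of them motors of the spindle such as Kif11 (136.7 and 48.2) and Kif2c (48.1 and 15.9). The 15 alpha protocadherin genes had a median of 0.84, but they share exons and cannot be counted as 15 separate measurements. Markers of microglia and of Cajal-Retzius cells (medians 1.72 and 1.48) moved with most of the GABA receptor, Camk and alpha protocadherin genes.

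The abundance of Dcx in the NPC library, 76.6% of its level in the neuron library, was weighed further. Exchanged labels are argued against, because 24 of 28 radial glia genes were at least 2-fold higher in the library labelled NPC. Carry-over of neurons like those of the neuron library is argued against as the whole source of Dcx, because it would bring every neuronal transcript to at least the same share, and 20 of the 23 other cytoskeleton genes lay below it by more than their counting intervals, with a median of 53.9% and a range of 15.1% to 86.2%. A smaller carry-over remains open. Per the labels, cells with both colours were gated into the neuron library. If so, it also stays open whether progenitors or young neurons that transcribe Dcx without passing the red gate are in the NPC library. Such cells may account for rank 5 of Dcx there. The gates are known from the labels alone, and the column names described below leave them uncertain.

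Markers of microglia and of blood vessel cells differed in opposite directions. The other cell types were not all raised together in 1 library, since the microglia and pericyte medians lay 4.92 apart on the log2 scale, with opposite signs. This restates the pattern and is no separate test of a lower share of cortical cells. These medians do not give the total share of cortical cells in either library, so a difference in that share stays open. Blood carried into one library was also looked at, and the erythroid median was −0.094. It stays open whether microglia were sorted along with the neuron library more than with the NPC library: all 14 markers were higher there by more than their counting intervals, 2.80-fold to 7.32-fold, with Csf1r at 46.8 and Mpeg1 at 37.0 CPM, although neither reporter gate was meant to admit them. It stays open in the same way whether pericytes and endothelial cells, which can transcribe Nes and might pass a green gate, were sorted along with the NPC library more than with the neuron library, where 20 of 22 markers were higher in NPCs by more than their counting intervals, with Abcc9 at 61.5 and Pdgfrb at 54.0 CPM. Both counts restate the pattern and cover counting error only, so they support neither explanation, and with 1 library per group a difference between the dissections cannot be told apart from one between the gates.

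For the higher synapse and ion channel transcripts of neurons, transcript length was weighed, since these genes are long (median 4880 bases for the synapse list and 8306 for the channel list, against 3555 for all genes past the filter). Among random lists matched on length and expression, the medians of the synapse list and of the channel list were both at percentile 100, and log2 ratio and length had a Spearman's rho of −0.037 across the 99.1% of genes with a length, so length is argued against as the cause. A difference between the cell types stays as a hypothesis, with the makeup of the sorted populations still open.

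A column name in each file begins with a letter, D in the NPC file and R in the neuron file, that the labels do not explain, while the labels describe green cells and cells with both colours. The grouping used here follows the labels, and so does the account of the gates given with the Dcx result. Gates other than those in the labels were not tested.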
